A study of Mus musculus with 6 samples.

How the data were processed

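Total RNA was taken from kidneys of male C57BL/6 mice aged 2 and 20 months, with 3 samples per age. Per the labels, RNA was extracted with Trizol, and cDNA was labelled with Cy3 by Klenow enzyme from random nonamers, so either strand can carry the label. Each sample was hybridised to an Agilent array of design 028005, scanned on a G2505C scanner at 3 micron and quantified with Agilent Feature Extraction 11.5.1.1, protocol GE1_1105_Oct12. Per the file headers, the processed signal intensity was background-subtracted and detrended within each array on a linear scale, with no scaling between arrays. The authors' value table is on the log2 scale: it equals the log2 processed signal, averaged per probe, minus each array's 75th percentile, so its scale and centring are known. The comparison started from the scanner intensities. The grid was annotated on mouse build mm9.

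Control spots and spots with a non-uniformity or population outlier flag were left out, and the spots of a probe were averaged on the log2 scale. Each array's 75th percentile of log2 signal was subtracted. A probe was tested where it was well above background on all arrays of at least 1 age, which left 30821 of 55681 probes. Of the 55681 probes, 26762 carried a single gene symbol, 28919 had none and 0 had several. Symbols came from the RefSeq annotation of build GRCm38.p6, which differs from the array's build, so no gene coordinates are given. A gene was represented by its probe with the highest mean over all 6 arrays, giving 20284 genes, of which 14549 were tested. The 75th percentile of processed signal was 4366, 4061 and 2892 on the young arrays and 4498, 4205 and 2702 on the aged arrays, and no probe was saturated.

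Aged and young samples were compared with limma (lmFit and eBayes, 2-sided), with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. A fold threshold of 2 was applied beside it, and the same test was run on single probes. Changes are aged minus young on the log2 scale, with the moderated standard error. A probe that was not well above background on any array of an age gives a lower bound of the fold, taken against the mean, over that age's arrays, of the lowest log2 signal well above background.

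Gene lists, the test, the filter, the scaling and the alternatives were chosen before the data were examined. The 45 lists cover cell types, pathways and complexes of the kidney. Of their 1140 members, 1138 matched a gene of the RefSeq annotation, though not all of these have a named probe on the array. Lists with at least 5 tested members were tested with camera at a preset correlation of 0.01, with adjustment over the lists. Camera compares a list's genes with all others. It was also run with an estimated correlation, under which 0 of 45 lists passed and 3 had an unadjusted p under 0.05, and fry, which asks whether a list's own genes move one way on balance, passed 1 list, that of B cells and plasma cells. Camera with the preset correlation passed 17 lists, 9 higher and 8 lower. For 4 lists that did not pass, the median and the direction of the test differed in sign. Members past the threshold are counted over all genes and adjusted over the list alone.

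The genes named were the 12 largest rises and 12 largest falls among genes past the threshold with non-overlapping groups, leaving out clone, predicted and accession names, and up to 4 members per list with the smallest p. Others are said to be chosen after their values were seen. The region probes named, which needed signal above background on all 6 arrays, were chosen in this way.

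The alternatives were quantile normalisation, median centring, the authors' values, no filter, a filter requiring signal on all 6 arrays, outlier spots kept, the mean of a gene's probes, eBayes with trend and robust, array weights, the replicate number, which is also the slide column, as a block, an unadjusted p with a 2-fold change, leaving out each array in turn, and the other list tests. Normexp (offset 50) was intended for the mean spot signal and was run on the median signal, a choice made after the data were seen. A slide block was not fitted, since all arrays lay on 1 slide.

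The procedure was tested on simulated data, with independent normal values for 14508 genes drawn from their own means and spreads and known changes added to some. It recovered 9 of 67 genes changed by 0.5 on the log2 scale (13.4%), 44 of 67 changed by 1 (65.7%) and 61 of 66 changed by 2 (92.4%), with 4 false calls among 118. With no change added it made 0 calls. Software was R 4.3.3 with limma 3.58.1, version 1.17.8 of data.table and jsonlite 2.0.0, and Python 3.11.15 with matplotlib 3.10.9 and numpy 2.4.6.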

Results

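Gene expression was measured in whole-kidney RNA of male C57BL/6 mice, an inbred laboratory strain, at the ages of 2 months (young) and 20 months (aged). There were 3 young and 3 aged samples, each hybridised to its own single-colour Agilent array. The labels name independent RNA preparations and do not say whether each came from a separate mouse, so p-values measure the spread between these samples, which may be partly technical. Of the 55681 probes, 72.9%, 69.0% and 55.3% were well above background on the young arrays and 62.9%, 55.8% and 46.3% on the aged arrays. The mean share was 65.7% ± 9.21 in young and 55.0% ± 8.31 in aged samples (SD, n = 3 each), with a two-sided exact permutation p = 0.3, where 0.1 is the smallest p this design allows. Same-numbered young and aged samples lay in the same slide column and had similar brightness. Within columns 1, 2 and 3 the aged share was lower by 9.99, 13.2 and 9.01 points (two-sided exact sign-flip p = 0.25, the smallest 3 columns allow). Log2 signal was correlated across the tested genes, with 1 probe each and values on all 6 arrays. The correlation was 0.989 to 0.993 between arrays of the same age and 0.977 to 0.987 between ages. Genes are not independent replicates. The number of arrays limits the precision of every value. All 6 arrays lay on 1 slide, young samples in slide row 1 and aged samples in slide row 2, so slide row and age cannot be told apart. The Y-linked genes Ddx3y, Eif2s3y and Uty were above background on all 6 arrays, while the probes of the Y-linked gene Kdm5d and of Xist were on 0.

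The comparison asked which genes differ in expression between young and aged kidney. Genes of B cells and plasma cells rose in aged kidney in 6 of 11 tested members (adjusted p = 0.43 with an estimated correlation). Jchain, the joining chain of secreted antibodies, was 17.4-fold higher (log2 change 4.12 ± 0.17, SE, n = 3 arrays per age, adjusted p = 0.00018), and Cxcl13, a chemokine that attracts B cells, rose by 2.99 ± 0.27. Cell cycle genes fell in 17 of 38 members and extracellular matrix genes in 6 of 33 (for both, adjusted p = 0.43 with an estimated correlation). Cdk1, the kinase that drives entry into mitosis, fell by 1.14 ± 0.16 and Col1a1, a chain of type I collagen, by 0.85 ± 0.12. Of 14549 genes tested with limma, 491 passed the adjusted p threshold of 0.05, 288 of them higher and 203 lower in aged kidney, and 203 of them changed at least 2-fold (134 higher, 69 lower). Without adjustment, 2493 genes had a p under 0.05. The aged and young arrays did not overlap for 3186 genes, 21.9% against the 10% that chance gives. Every gene named here as changed had non-overlapping groups. The count was 161, 242 and 236 without young replicates 1, 2 and 3, and 922 (344 higher, 578 lower), 141 and 244 without aged replicates 1, 2 and 3. The 2-fold count was 133 without young replicate 1, 404 (142 higher, 262 lower) without aged replicate 1 and 107 without aged replicate 2. Of the 80 genes named from these lists and ranks that passed, leaving out aged replicates 1, 2 and 3 ended 8, 46 and 25 calls and leaving out young replicates 1, 2 and 3 ended 40, 23 and 26. No filter on dim probes ended 75 calls, the slide column as a block 20 and normexp 17. The count was 303 (213 higher, 90 lower) with normexp background correction, where 115 genes were higher and 32 lower at least 2-fold, 773 with median centring (396 higher, 377 lower), 776 with array weights (425 higher, 351 lower), 266 with the slide column as a block (164 higher, 102 lower) and 16 with no filter on dim probes (15 higher, 1 lower). At least 2-fold, median centring gave 198 higher and 150 lower, and no filter 15 higher and 1 lower.

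Among the largest rises, Jchain was measured above background on all 6 arrays. Mir124-2hg, the host transcript of a microRNA best known from neurons, was above background on 0 of 3 young arrays and was at least 28.8-fold higher in aged kidney on the processed signal. Prg2, a granule protein of eosinophils, and the olfactory receptor Olfr1317 were also above background on 0 of 3 young arrays and were at least 9.71-fold and 6.33-fold higher. Neurog2, a transcription factor of nerve cell formation, rose by 4.35 ± 0.40 and was above background on 1 young array. Magea1 and Magea3, genes normally active in testis, rose by 5.37 ± 0.43 and 3.67 ± 0.35. The steroid sulfotransferases Sult2a2, Sult2a3, Sult2a6 and Sult2a1 rose by 4.75, 4.66, 3.98 and 3.51, and Cyp2b10, a drug-metabolising enzyme, by 3.50. These 7 genes were above background on 2 of 3 young arrays each, and the closely related Sult2a genes may share signal between probes. With normexp background correction, whose added offset shrinks changes of dim probes, the log2 changes of Mir124-2hg, Prg2 and Olfr1317 were 3.81, 2.73 and 2.30, and those of Neurog2, Magea1 and Magea3 were 2.91, 3.69 and 2.58. Those of Sult2a2, Sult2a3, Sult2a6, Sult2a1 and Cyp2b10 were 3.52, 2.92, 2.59, 2.74 and 2.03. Without young replicate 2 the changes of Sult2a2, Sult2a3, Sult2a6 and Cyp2b10 were 5.37, 5.47, 4.77 and 4.18, and without young replicate 3 those of Sult2a3, Sult2a6 and Cyp2b10 were 4.08, 3.34 and 2.84. The adjusted p passed 0.05 without aged replicate 2 for Sult2a3 (0.0606), and without several arrays for Sult2a6 (up to 0.0935) and Cyp2b10 (up to 0.126), which was also 0.0530 with quantile normalisation and 0.0503 with a trended robust variance.

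The largest fall measured on all 6 arrays was that of Slc14a2, the urea transporter of the inner medullary collecting duct, which fell by 3.98 ± 0.80. It had normalised log2 signals of 0.05, -3.61 and -2.70 on aged replicates 1, 2 and 3 and 1.68 to 2.03 on the young arrays, and its change was -5.05 without aged replicate 1 and -3.22 without aged replicate 2. Akr1c18, a progesterone-metabolising reductase, fell by 2.17 ± 0.31, Mogat2, an enzyme of triglyceride synthesis, by 1.88 ± 0.17, Cryaa, a lens crystallin, by 1.88 ± 0.22 and Upk3b, a urothelial plaque protein, by 1.79 ± 0.23. The chloride channel family gene Clic6 (-1.93 ± 0.12), Wnt11 (-2.02 ± 0.26), Pjvk (-2.09 ± 0.29) and Adamts8 (-2.47 ± 0.39) also fell, each above background on 2 of 3 aged arrays, while another probe of Adamts8 changed by -0.15 and the mean of its probes by -1.31. Tex21 fell by 2.14 ± 0.27 and Elf5, a transcription factor of principal cells, by 2.21 ± 0.44, both above background on 1 aged array. Mmp1b, a collagenase, was above background on 0 of 3 aged arrays and at least 2.75-fold lower, against 2 young arrays, since its spot on young replicate 2 was left out as an outlier. With normexp the changes were -1.06 for Tex21, -1.06 for Elf5 (adjusted p = 0.0848), -1.16 for Pjvk, -1.38 for Wnt11, -1.75 for Adamts8 and -2.00 for Mmp1b. Mogat2, Cryaa, Upk3b, Clic6 and Tex21 kept their calls whichever array was left out. Without aged replicate 2 the adjusted p was 0.0679 for Akr1c18, 0.0558 for Pjvk and 0.0547 for Wnt11, while Slc14a2 (up to 0.137), Elf5 (up to 0.117), Mmp1b (up to 0.112) and Adamts8 (up to 0.0666) lost their calls in 3 to 5 of the 6 leave-one-out fits (for Mmp1b, 2 of these fits had 1 young value, assumed to vary like the rest), Mmp1b also with the slide column block (0.0865), and Slc14a2 with quantile normalisation (0.0556) and a trended robust variance (0.176).

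Genes of B cells and plasma cells, a list fixed in advance like all those that follow, rose in part in aged kidney. Of 11 tested members, 6 were higher, 0 lower and 5 not past the threshold (7 higher adjusted over the list alone, median log2 change 1.04). Changes were above 0 for 7 members and below 0 for 4, with none of these 4 past the threshold. Pou2af1, a coactivator of antibody genes, rose by 2.70 ± 0.16, Mzb1, a chaperone of antibody secretion, by 1.85 ± 0.11 and Fcrla by 1.38 ± 0.17. In the list of T cell and natural killer cell genes 7 of 24 rose (14 adjusted over the list alone, median 0.70). These included the adhesion receptor Cd2 (1.16 ± 0.16), Cd5 (0.71 ± 0.10), the chemokine receptor Cxcr6 (0.98 ± 0.15) and the chemokine Ccl5 (1.05 ± 0.17). Of its changes 20 were above 0 and 4 below: Gzma (-0.75), Prf1 (-0.36), Cd4 (-0.24) and Ncr1 (-0.07), with none of these past the threshold. Klrd1 changed by 0.72 (adjusted p = 0.143) and Gzmb by 0.04. Macrophage and dendritic cell genes rose in 3 of 18 (11 adjusted over the list alone, median 0.51): Itgax, the integrin of dendritic cells (0.99 ± 0.13), Flt3 (0.72 ± 0.13) and C1qc (0.68 ± 0.14). On young replicates 1, 2 and 3 the macrophage median was -0.49, -0.26 and -0.01 and the T cell median -0.60, -0.28 and -0.17. The chemokine, complement, class I and adipocyte lists below had the same order. The B cell list (-0.43, -0.82 and -0.31) and the class II list below did not. The camera adjusted p was 7.62e-06 for the B cell list, 9.04e-09 for the T cell list and 3.69e-09 for the macrophage list; for each, adjusted p = 0.43 with an estimated correlation, and fry gave 0.0159, 0.0781 and 0.0946. Jchain, Pou2af1, Mzb1, Fcrla and Itgax kept their calls whichever array was left out. The adjusted p of Cd2 was 0.0525 without aged replicate 2 and those of Cd5, Cxcr6, Ccl5, Flt3 and C1qc reached 0.0658, 0.0759, 0.0995, 0.122 and 0.162. The adjusted p of Cd5 and Flt3 was 0.139 and 0.133 with normexp, that of Cd5 0.0922 with a trended robust variance, that of C1qc 0.0501 with median centring, and the slide column block ended the calls of Cd2, Ccl5, Flt3 and C1qc (0.0536 to 0.0797).

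Chemokines and cytokines rose in 4 of 31 members (9 adjusted over the list alone; median 0.34). Besides Cxcl13 and Ccl5, these were Ccl8, an attractant of monocytes (2.15 ± 0.29), and Ltb, a lymphotoxin of lymphoid tissue formation (0.88 ± 0.12). Complement genes rose in 3 of 19 (5 adjusted over the list alone; median 0.46): C4b by 1.71 ± 0.22, C6, a part of the membrane attack complex, by 1.79 ± 0.27, and C1qc. Class II antigen presentation genes rose in 3 of 11 (8 adjusted over the list alone; median 0.41), namely the peptide-loading genes H2-DMa (0.83 ± 0.11) and H2-Oa (0.79 ± 0.13) and the protease Ctss (0.64 ± 0.13), while Cd74 changed by 0.49 ± 0.15 (adjusted p = 0.152). Of the class I genes, H2-M3 alone rose (0.52 ± 0.11), 1 of 18 (2 adjusted over the list alone; median 0.11). The camera adjusted p was 9.04e-09, 2.33e-06, 3.26e-07 and 0.00377 for these 4 lists in order; for each, adjusted p = 0.43 with an estimated correlation, and the class I value was 0.0889 without aged replicate 1. The class I median was 0.18 without aged replicate 2, the complement median 0.31 without young replicate 1 and the chemokine median 0.64 with no filter on dim probes. Cxcl13 kept its call whichever array was left out. Without aged replicate 2 the adjusted p was 0.0522 for C4b and 0.0575 for Ccl8. Without young replicate 1 it was 0.0557 for Ltb. H2-M3 lost its call in all 6 leave-one-out fits (up to 0.161), Ctss in 5 (up to 0.174), H2-Oa in 4 (up to 0.0777), and H2-DMa and C6 in 2 each (up to 0.0540 and 0.0578). H2-M3, Ctss and H2-Oa also lost it with normexp (0.0997, 0.0695 and 0.0985) and the slide column block (0.0958, 0.0599 and 0.0519). So did H2-M3 and Ctss with median centring (0.128 and 0.0687).

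Cell cycle genes fell: 17 of 38 tested members were lower and 0 higher (25 lower adjusted over the list alone; median -0.78). Bub1, a kinase of the spindle checkpoint, fell by 1.47 ± 0.19, the mitotic kinase Plk1 by 0.96 ± 0.13 and Cdca8, a subunit of the chromosomal passenger complex, by 0.90 ± 0.13. Bub1 was above background on 1 aged array and Plk1 on 2. Extracellular matrix genes fell in 6 of 33 and rose in 1 (10 lower and 2 higher adjusted over the list alone; median -0.26). Eln, the elastic fibre protein elastin, fell by 1.76 ± 0.23 and was above background on 1 aged array. The fibrillar collagen chains Col3a1 and Col5a2 fell by 0.96 ± 0.15 and 0.82 ± 0.12. The member that rose was Timp1, an inhibitor of matrix proteases (1.26 ± 0.21). The camera adjusted p was 4.15e-15 for cell cycle and 9.95e-05 for matrix genes; for both, adjusted p = 0.43 with an estimated correlation, and fry gave 0.0653 and 0.0781. Cdk1 and Eln kept their calls whichever array was left out. Without aged replicate 2 the adjusted p was 0.0557 for Bub1 and 0.0522 for Plk1, and those of Cdca8, Col1a1, Col3a1, Col5a2 and Timp1 reached 0.0674, 0.0626, 0.0826, 0.0548 and 0.0976. With normexp the changes of Eln, Bub1, Plk1 and Cdca8 were -0.86, -0.73, -0.56 and -0.78 and did not pass (adjusted p = 0.0716, 0.0877, 0.0979 and 0.0519). Bub1 did not pass with quantile normalisation (0.0538), nor Col3a1 with the slide column block (0.0560).

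Lists of collecting duct, intercalated and loop of Henle cells had small negative medians, with few members past the threshold. Collecting duct principal cell genes fell in 2 of 13 (5 adjusted over the list alone; median -0.20), Elf5 and Kcne1, a potassium channel subunit (-0.63 ± 0.12). Intercalated cell genes fell in 1 of 15 (1 adjusted over the list alone; median -0.24), the ammonia transporter Rhbg (-0.59 ± 0.12), and loop of Henle genes in 1 of 13 (1 adjusted over the list alone; median -0.14), Bst1 (-1.13 ± 0.17). Slc12a1, the sodium transporter of the thick ascending limb, changed by -0.25 ± 0.11 (adjusted p = 0.318). Distal convoluted tubule genes were not called: with limma 0 of 12 passed and 3 had an unadjusted p under 0.05 (2 lower adjusted over the list alone; median -0.11; camera adjusted p = 0.615; fry 0.0879), and Slc12a3, its sodium chloride transporter, changed by 0.37 ± 0.12 (adjusted p = 0.18). The camera adjusted p was 0.00234 for principal cells, 0.00175 for intercalated cells and 0.0114 for the loop of Henle; adjusted p = 0.61 with an estimated correlation for principal cells and 0.43 for the others. The principal cell value was 0.0507 without aged replicate 1, and the loop of Henle value was 0.0995 without aged replicate 2 and 0.0725 with median centring. The principal cell median was -0.36 without aged replicate 3 and -0.30 with array weights. Urothelium genes had a median of -1.18 over 11 members with Upk3b alone past the threshold (1 adjusted over the list alone; camera adjusted p = 0.00234; adjusted p = 0.73 with an estimated correlation). That list rested on young replicate 1, whose median over the list was 2.24 against -0.14 and -0.10 on the other young arrays. Without it the median was -0.43 (adjusted p = 0.0144), and over members above background on all 6 arrays it was -0.45. Rhbg, Kcne1 and Bst1 lost their calls in several leave-one-out fits, with an adjusted p of up to 0.172, 0.155 and 0.0747. Rhbg and Kcne1 also lost them with normexp (0.111 and 0.0601), median centring (0.12 and 0.0775) and the slide column block (0.0928 and 0.0840).

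Adipocyte genes rose in 1 of 10 members (3 adjusted over the list alone; median 0.87): Plin4, a coat protein of lipid droplets (1.78 ± 0.32). Adipoq, the adipocyte hormone adiponectin, changed by 1.72 ± 0.55 (adjusted p = 0.161), and the list's median was -1.31, -0.39 and 0.11 on the young and 0.50, 0.19 and 0.49 on the aged arrays. Tubular injury genes rose in 3 of 22 (5 adjusted over the list alone; median 0.06): Timp1, the matricellular protein Ccn1 (1.07 ± 0.14) and the copper carrier Cp (0.97 ± 0.17). The camera adjusted p was 0.00858 and 0.0254; for both, adjusted p = 0.43 with an estimated correlation. The adipocyte value was 0.0607 without aged replicate 1, and the injury value 0.0740 without young replicate 3, 0.0573 without aged replicate 2 and 0.215 with no filter on dim probes. The adipocyte median was 0.53 without young replicate 1 and 1.32 without young replicate 3, and the injury median 0.11 without aged replicate 1 and 0.10 with the mean of a gene's probes. Ccn1 kept its call whichever array was left out, while the adjusted p of Plin4 and Cp reached 0.116 and 0.0824 with an array left out and was 0.0639 and 0.0575 with the slide column block.

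Fatty acid oxidation and peroxisome genes fell in 1 of 44 (1 adjusted over the list alone; median -0.12): Cyp4a14, a fatty acid hydroxylase, fell by 1.19 ± 0.14 and kept its call whichever array was left out. Oxidative phosphorylation genes had a median of -0.09 over 46 members; with limma 0 passed over all genes or adjusted over the list alone, and 2 had an unadjusted p under 0.05. The camera adjusted p was 0.0254 and 0.0330; adjusted p = 0.78 with an estimated correlation for both. The fatty acid value was 0.158 without young replicate 2, 0.157 without aged replicate 1, 0.114 without aged replicate 2 and 0.127 with median centring. The oxidative phosphorylation value was 0.132, 0.0871, 0.157 and 0.466 without young replicates 2 and 3 and aged replicates 1 and 2, and 0.0520, 0.245, 0.0520 and 0.0509 with quantile normalisation, median centring, the mean of a gene's probes and the slide column block. Its median was -0.06, -0.04 and -0.18 without aged replicates 1, 2 and 3. Outside the 17 called lists, the cholesterol synthesis gene Cyp51, a sterol demethylase, fell by 0.99 ± 0.11, 1 of 23 members (1 adjusted over the list alone; camera adjusted p = 0.0547).

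**Figure D1:**
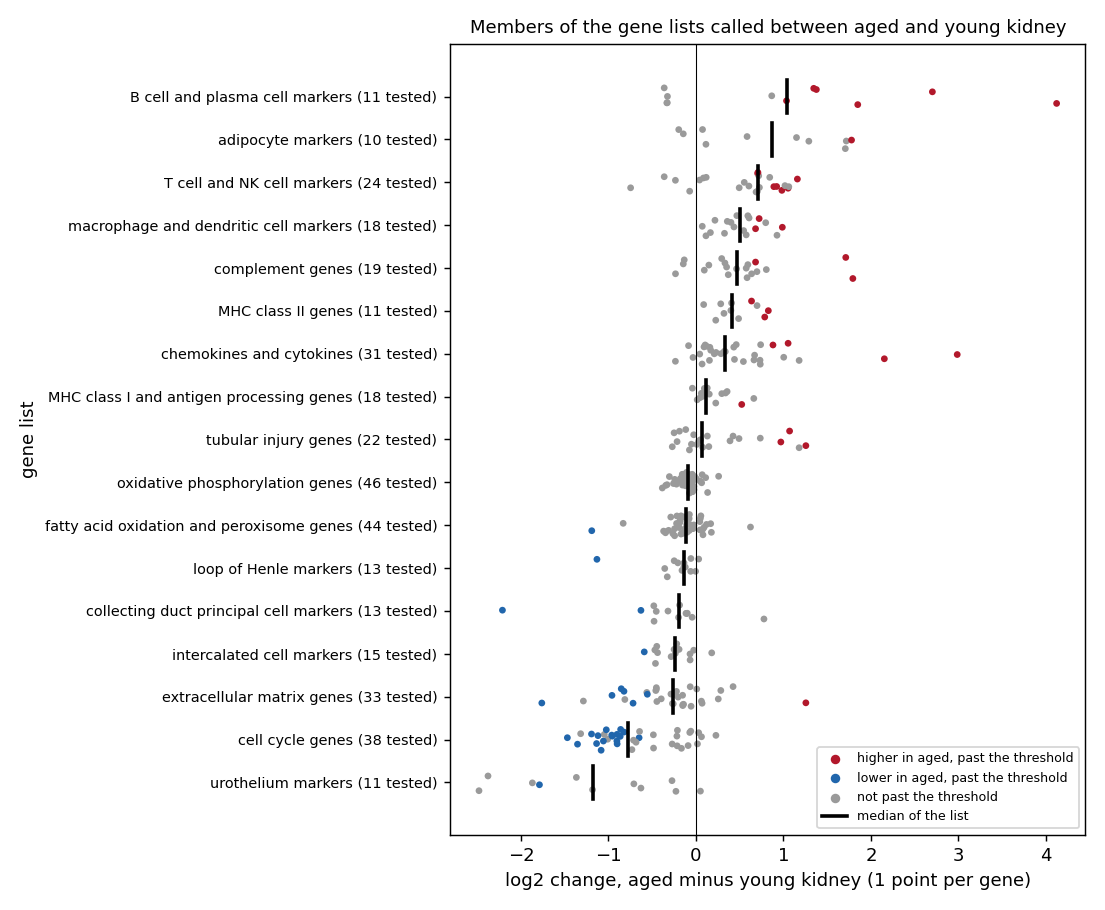
Log2 change (aged minus young) of every tested member of the 17 called gene lists, where each point is a gene coloured by whether it passed the adjusted p threshold and each black bar is the list's median. The cell cycle median lay at -0.78 and the B cell and plasma cell median at 1.04.

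**Figure D2:**
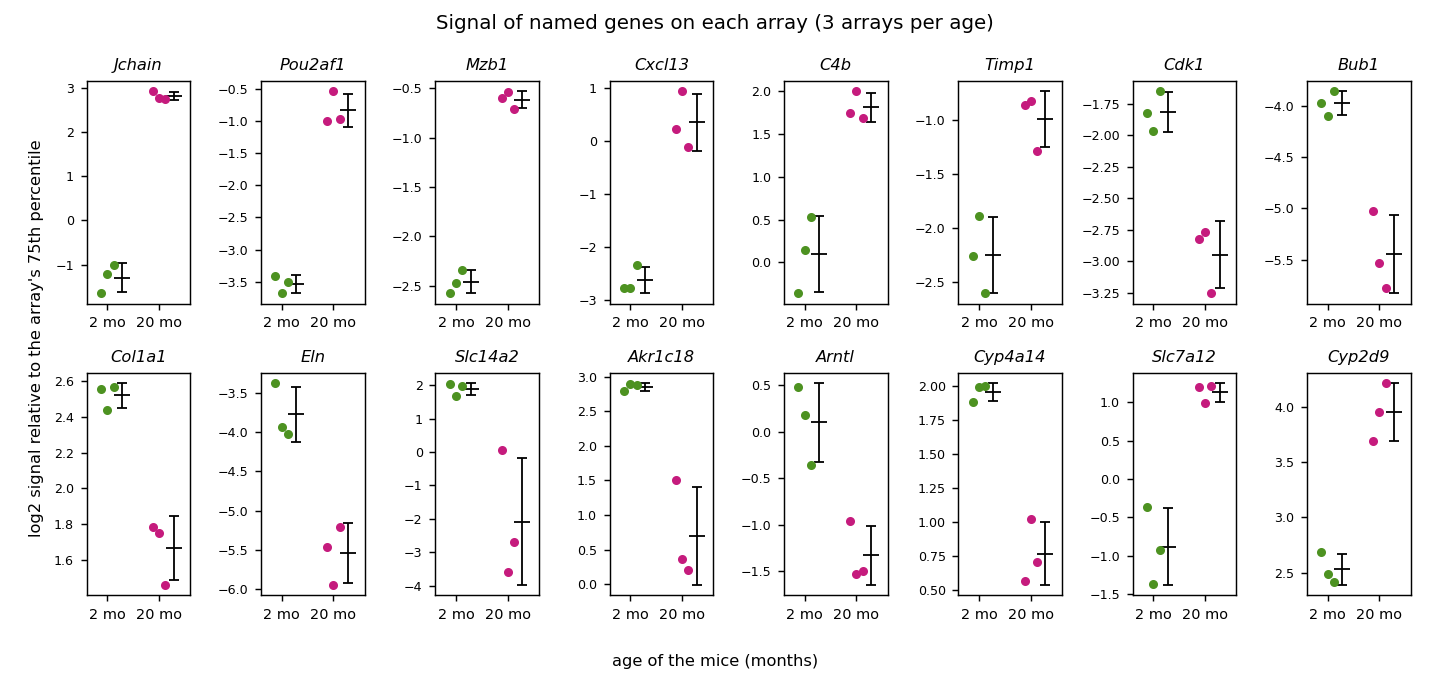
Normalised log2 signal of 16 named genes on the 3 young and 3 aged arrays, with points for single arrays and bars for the mean ± SD, on a separate scale for each gene; these genes were picked for the plot after their values were seen. Jchain had a mean of -1.30 in young and 2.82 in aged samples.

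Probes without a gene name were also tested. Of 30821 probes, 643 changed (456 higher, 187 lower): 348 of 18861 with a gene name, 52 of 6010 for chromosomal regions and 243 of 5950 for other accessions (209 higher, 34 lower). The count was 309 (281 higher, 28 lower), 329 (272 higher, 57 lower) and 367 (314 higher, 53 lower) without young replicates 1, 2 and 3. It was 2035 (599 higher, 1436 lower) and 314 (273 higher, 41 lower) without aged replicates 1 and 2. With no filter on dim probes it was 105 (103 higher, 2 lower). Among region probes above background on all 6 arrays, signal rose most at chromosome 1, 122655019 to 122660142 (mouse build mm9), by 2.96 ± 0.27, and at chromosome 1, 167218236 to 167218418, by 2.87 ± 0.24. At chromosome 8, 74439200 to 74441363, it fell by 0.82 ± 0.12. The labelling copies either strand, so a transcript and its antisense partner cannot be separated.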

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

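The normexp setting was chosen only after the data were seen; the others were set beforehand. The 491 changed genes became 303 with normexp (278 shared), 773 with median centring (409 shared), 776 with array weights (484 shared), 266 with the replicate number, which is also the slide column, as a block (240 shared) and 16 with no filter on dim probes (15 shared). Leaving out each array gave 141 to 922 genes, the highest without aged replicate 1 (427 shared). Genes changed at least 2-fold, 203 of them, became 348 with median centring, 16 with no filter and 107 to 404 with an array left out. The 643 changed probes became 105 with no filter and 309 to 2035 with an array left out. With no filter 20284 genes were tested in place of 14549, yet 2279 had an unadjusted p under 0.05 with limma, against 2493. The cause of these moves, including the fall with no filter and the higher counts without aged replicate 1, was not tested. Probes were run under no other setting. The 17 called lists became 14 to 21 with an array left out, 1 with fry and 0 with an estimated correlation. The remaining settings kept the total counts of genes, of 2-fold genes and of lists within 1.5 times. The split by direction moved more. At least 2-fold, requiring signal on all 6 arrays gave 122 higher and 38 lower genes, and array weights 159 and 115, against 134 and 69. Among the tested genes, 40 were above background on all young and no aged arrays, and 3 the reverse. Among values for single genes and lists, 3664 kept their direction and side of the threshold under an alternative, 351 no longer passed, 108 newly passed and 0 changed sign. Of the 80 named genes past the threshold, 27 kept the call whichever array was left out; leaving out aged replicate 2 ended 46 calls and young replicate 1 ended 40. No setting moved the median of all genes by more than 0.0552. Deviations of same-numbered samples correlated across genes at 0.062, -0.092 and 0.102, and replicate 3 alone correlated best with its own number, so the numbers were not taken to pair the samples; same-numbered arrays did share a slide column and similar brightness. Signal over background, 46.3% to 72.9% of probes, limits what dim genes can show.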

Other observations

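The tests of fat, blood and weaker detection on the aged arrays were chosen only after the result was seen. So was the rule that a 95% bootstrap interval over a list's members must lie on 1 side of a bound. Such an interval treats genes as independent and leaves out the spread between samples. On the medians alone, the lymph node test had met its bound and the first blood test, the inner medulla test and the cell cycle test had counted against their explanations.

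Genes with a known sex bias in kidney moved in both directions. Of 23 male-biased genes, Cyp2d9 (1.42 ± 0.16), Cyp4a12a (1.00 ± 0.14) and Cyp4a12b (0.90 ± 0.13), all cytochrome P450 enzymes, rose, and 0 fell (3 higher adjusted over the list alone; camera adjusted p = 0.605). Of 10 female-biased genes, the amino acid transporter Slc7a12 (2.01 ± 0.23) and the peroxisomal oxidase Hao2 (0.56 ± 0.12) rose and Cyp4a14 fell (4 higher and 2 lower adjusted over the list alone; camera adjusted p = 0.330). Of 17 circadian clock genes, Arntl, a core activator of the clock, fell by 1.43 ± 0.24 and was the only member past the threshold over all genes. Adjusted over the list alone, 5 members were higher and 2 lower (camera adjusted p = 0.330, 9 changes above 0 and 8 below). Npas2, above background on 1 of 3 aged arrays, had a lower signal in aged kidney (adjusted p = 0.0795), and Ciart and Bhlhe40 changed by 0.76 ± 0.18 and 0.70 ± 0.18 (adjusted p = 0.0644 and 0.0903). The labels give no time of day for tissue collection. Cyp2d9, Cyp4a12a and Slc7a12 kept their calls whichever array was left out, while Cyp4a12b, Hao2 and Arntl reached an adjusted p of 0.0707, 0.177 and 0.103. Hao2 also lost its call with normexp (0.0756), median centring (0.118), the authors' values (0.0512) and the slide column block (0.0731).

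Of 37 genes of amino acid metabolism, 3 rose and 0 fell (3 higher adjusted over the list alone): Hpd, of tyrosine breakdown (1.25 ± 0.18), Bhmt, which remethylates homocysteine (1.13 ± 0.20), and the alanine transaminase Gpt (0.81 ± 0.12; camera adjusted p = 0.0892). The glycolytic enzyme Hk2 rose by 1.04 ± 0.15, 1 of 27 in the list of glycolysis and gluconeogenesis (1 adjusted over the list alone; camera adjusted p = 0.779). The hypoxia list of 22 genes had 2 rises, the vasoconstrictor Edn1 (0.81 ± 0.12) and the carbonic anhydrase Car9 (0.93 ± 0.14), and 1 fall, Angpt2 (-0.87 ± 0.16), with 7 changes above 0 and 15 below (3 higher and 2 lower adjusted over the list alone; camera adjusted p = 0.658). In the senescence and p53 list, Phlda3 (0.79 ± 0.13) and the macrophage elastase Mmp12 (0.82 ± 0.17) rose, 2 of 29 (4 higher and 2 lower adjusted over the list alone; camera adjusted p = 0.447), while Cdkn1a, the p21 inhibitor of cell division, changed by 0.48 ± 0.11 (adjusted p = 0.0641) and by -0.08 on another probe. The podocyte gene Npnt fell by 0.78 ± 0.14, 1 of 15 (1 adjusted over the list alone; camera adjusted p = 0.378). Mc2r, the receptor for corticotropin, rose by 2.25 ± 0.31, 1 of 5 adrenal markers (1 adjusted over the list alone, camera adjusted p = 0.491). The adrenal list had a median of -0.46, with 1 change above 0 and 4 below. Mc2r rose by 1.59 with normexp, and its adjusted p was 0.0606 without aged replicate 2. Each of the other changed genes in this paragraph lost its call without at least 1 array, with adjusted p of up to 0.157. With normexp the adjusted p was 0.113 for Hk2 and 0.124 for Npnt, with quantile normalisation 0.0696 and a trended robust variance 0.0758 for Mmp12, and the slide column block ended the calls of Hk2, Npnt, Mmp12 and Angpt2 (0.0516 to 0.111).

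Splits of the 6 arrays into 3 and 3 number 10, too few for a share under 0.05. The real split gave 491 genes, 203 genes at 2-fold and 643 probes. The highest of the other splits gave 0 of each with limma, so 1 split was as large for each count. At an unadjusted p under 0.05 the other splits gave 128 to 1596 genes against 2493. The 1596 came from young replicates 1 and 2 with aged replicate 1 against the rest. Those 3 arrays had the largest shares of probes above background. The next highest of the other splits gave 590. The real split called 17 lists and the highest of the others 23, the split of young replicates 1 and 2 with aged replicate 3 against the rest, and 3 of the 10 splits called at least 17. Of the 17 lists, 11 had their largest median change in the real split and 1 was called in it alone. Camera's preset correlation thus also called lists in splits that mix the ages. Each of those splits is unequal in age and keeps part of any age difference, so its calls need not be false.

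The rise of lymphocyte, plasma cell and macrophage genes may have come from immune cells in the aged kidney, from tissue carried along or from blood. More whole blood left in the aged samples was argued against only in that haemoglobin genes did not rise. The highest log2 change plus 2 SE over 5 haemoglobin genes was 0.27. That lies below a bound of 0.5, which was set after these values had been seen and so adds no support. All 5 changed by -0.15 to -0.42, with none past the threshold. The platelet genes Ppbp (0.69 ± 0.14, past the threshold) and Pf4 (0.65 ± 0.18, adjusted p = 0.11) went the other way. Ppbp lost its call in all 6 leave-one-out fits (adjusted p up to 0.136) and with normexp (0.149). Platelets or white cells apart from red cells stay open. A first blood test, the median of 9 blood markers (-0.15, interval -0.24 to 0.65), decided nothing and was replaced once the haemoglobin values had been seen. Lymph node and perirenal fat carried into the aged samples stay open, since 7 tested lymph node genes had a median of 0.74 (interval 0.18 to 1.19), Ccr7 alone past the threshold and 1 shared with the chemokine list, lymphoid tissue formed in the kidney would express these genes too, Glycam1 was above background on 0 arrays, and 3 of 10 adipocyte markers had all aged above all young arrays. Age itself and slide row were not tested and stay open.

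The fall of collecting duct, intercalated cell, loop of Henle and urothelium genes could follow weaker detection on the aged arrays. It could also follow a smaller share of inner medulla. Weaker detection here means a lower share of probes above background. The median processed signal was similar, at 284, 247 and 157 on the young and 296, 241 and 146 on the aged arrays. A shift shared by all genes of like signal would also have moved random lists matched on signal. The median of the 46 members above background on all 6 arrays was -0.22. That was percentile 0 of 10000 random lists matched on signal, whose 5th to 95th percentiles were -0.06 to 0.05. The random lists show only that genes of like signal did not fall alike. The percentile itself adds no support, since the tested lists were picked for their fall and random lists draw genes independently. Other effects of weaker detection stay open. Less inner medulla in the aged samples stays open. The 13 medullary genes tested had a median of -0.18, with an interval of -0.20 to 0.10 that reaches the -0.2 bound set before the result. Of these genes, 7 are also in other lists, among them Aqp2, Aqp3, Aqp4 and Fxyd4 in the principal cell list. Slc14a2, of the inner medullary collecting duct, is not among the 13. It was named as a largest fall and fell by 3.98 ± 0.80, unevenly across the aged arrays. Slide row and age itself were not tested.

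The fall of cell cycle genes was set against the same explanations. For weaker detection, a shift shared by all genes of like signal would again have moved matched random lists. The median of the 28 members above background on all 6 arrays was -0.65. That was percentile 0 of random lists matched on signal (-0.11 to 0.10). The random lists again show only that genes of like signal did not fall alike. This list too was picked for its fall, so the percentile adds no support. Other effects of weaker detection stay open. The cell cycle median minus the inner medulla median was -0.60 (interval -0.97 to -0.31). This interval over genes excludes 0 and includes the -0.4 bound, but it leaves out the spread between samples. Less inner medulla in the aged samples therefore stays open. Slower cell division in kidneys past growth, as the ages would give, is a candidate explanation that was not tested, and slide row stays open.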
